A study of Mus musculus with 4 samples.

How the data were processed

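Tibialis anterior muscle, a leg muscle, was taken from mice of the Dmd Dup2 model, which carry a duplication of exon 2 of the dystrophin gene. One group was untreated and the other had received scAAV9.U7-ACCA, a self-complementary adeno-associated virus of serotype 9 that delivers a U7 small nuclear RNA for exon skipping. Per the labels' protocols, frozen muscle was homogenised with cycloheximide, which holds ribosomes on the mRNA, and part of each homogenate was used to isolate ribosome-protected fragments (footprints). RNA-seq libraries came from a stranded total RNA kit and footprint libraries from a small RNA kit, and reads were 50 nt long. There were 4 libraries, 1 per group: mRNA untreated, mRNA treated, footprints untreated and footprints treated.

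The authors deposited 1 table of 1000 genes, each named by a symbol and a RefSeq identifier. Per the file headers it gives for each library a read count, and the values are whole numbers with a different total in each library. It also holds normalized read counts, per the file headers. These deposited values equal the count times 1 constant per library in 100% of genes, within 0.1, and they were read as CPM. That scale was inferred from the values, since in every library the listed genes sum to less than the CPM total of a whole library, and it is not stated whether the constant holds a normalization factor. Trimmomatic, STAR, edgeR and the mouse genome build mm9 are named in the submitters' processing notes, without roles or versions. The counting tool, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The rows stand in falling order of the untreated mRNA count, which reaches down to 14 reads, so the listed genes are those with the most reads in that 1 library. A gene with few reads in untreated muscle and many in treated muscle would therefore be missing from the table. Of the 1000 RefSeq identifiers, 996 were found in the RefSeq gene table of assembly GRCm38.p6, which was used for names alone, and 76 symbols differed from the current ones. The symbols are given here as in the deposited table.

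Analyses used the raw counts. Library scaling used TMM from edgeR 4.0.16 in R 4.3.3 over the listed genes. For each gene the treated to untreated ratio of scaled reads was taken in mRNA and in footprints, with an exact conditional binomial 95% interval. Translation efficiency, the footprint ratio divided by the mRNA ratio, was computed with 0.5 added to each count and has a 95% normal interval on the log scale. With 1 library per group no model with an estimated spread could be fitted, so no test between conditions was made and no p-value is given. The intervals cover counting error only. Reads carried no molecular identifiers, so they are not independent molecules. A gene was called higher or lower when it differed by at least 1.5-fold, its interval excluded 1 and it had at least 50 reads summed over the compared pair of libraries. For translation efficiency each pair had to reach that minimum. Such a call compares these libraries, not the conditions.

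The named genes followed a rule written before the data were examined. They are the 12 highest and 12 lowest genes in mRNA and in footprints, and the 6 highest and 6 lowest in translation efficiency, ranked by the interval bound nearest to no difference. Dmd and Utrn were added wherever listed, with up to 4 examples from each of 25 gene lists. A few genes that the rule names are not reported here. Those lists, fixed at the same time, were the dystrophin-associated complex, immature and regenerating fibre, extracellular matrix and fibrosis, macrophage and innate immune cell, T and B lymphocyte, interferon response and antigen presentation, fast contractile, slow contractile, sarcomere scaffold and mechanical stress, calcium handling, glycolysis and glycogen, nuclear oxidative phosphorylation genes, citrate cycle and fatty acid oxidation, mitochondrially encoded genes, translation factors, atrophy and muscle mass control, immediate early and heat shock, red blood cell, adipocyte, endothelial and smooth muscle, Schwann cell and nerve, tendon, abundant noncoding RNA, sex-linked genes and cytosolic ribosomal proteins. For each of the 16 lists with at least 3 listed members, the median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 10 bins. Genes under the minimum of 50 reads were left out of medians and random lists. The percentile describes these libraries and is not a test of the treatment. Intervals of list medians came from 1000 draws of Poisson counts.

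Alternatives were other scalings (DESeq2 1.42.0 size factors, the listed total, the upper quartile and the total without the 20 most abundant genes), no minimum or a minimum of 200 reads, and a 2-fold threshold. For the correlation alone, 5 was added to each count, or ribosomal protein, histone and mitochondrially encoded genes were left out. The values of these correlation alternatives are not reported here. After the data were seen, the authors' library constants, genes with at least 100 untreated mRNA reads, thinning of all libraries to 125236 reads, and random lists matched on the untreated mRNA count were added. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

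The steps were tested on simulated counts for the 1000 genes, 200 of them changed by a known fold. As many genes were raised as lowered, and each moved in opposite directions in mRNA and footprints. The rates below therefore do not cover errors of library scaling when changes are more frequent or lie mostly on one side. With counting error alone, 79% of genes changed 2-fold were called in mRNA and 98% in footprints, and 99% of those changed 4-fold in each. For translation efficiency 100% of genes changed 4-fold were called. Unchanged genes were called in 2.5%, 0.3% and 3.1% of cases in mRNA, footprints and translation efficiency. With an added coefficient of variation of 0.4 between libraries, unchanged genes were called in 45.2%, 51.9% and 57.4% of cases. The true variation between animals cannot be estimated with 1 library per group.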

Results

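The deposited data compared mRNA levels and ribosome footprints in tibialis anterior muscle of untreated Dmd Dup2 mice and of mice that had received the exon-skipping vector. Footprints are the mRNA fragments covered by ribosomes, and their number follows how many ribosomes are on a gene's mRNA. Each of the 4 groups had 1 library, so no difference below has a replicate check. The labels do not state how many animals each library holds, their age or sex, or whether animals were pooled. The listed genes held 125236 reads in the untreated mRNA library, 4248818 in the treated mRNA library, 3349015 in the untreated footprint library and 1664122 in the treated footprint library. The median gene had 25, 705, 626 and 297 reads in the same order, and 996 of the 1000 genes had fewer reads in the untreated than in the treated mRNA library, so its depth limits the precision of most mRNA ratios. The median half-width of the 95% interval was 0.62 on the log2 scale in mRNA, 0.21 in footprints and 0.63 in translation efficiency.

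Myosin heavy chain genes and Ttn were among the most abundant genes. Myh4, the fast myosin heavy chain of type IIb fibres, held 9.06% (95% exact binomial interval 8.91 to 9.22) of the listed reads in untreated mRNA and 8.79% (8.76 to 8.82) in treated mRNA. It held 9.30% (9.27 to 9.33) and 10.7% (10.6 to 10.7) of untreated and treated footprints. Ttn, which encodes the giant sarcomere spring titin, took 8.67% (8.51 to 8.82) of untreated mRNA reads and 26.5% (26.5 to 26.6) of treated mRNA reads. The 20 most abundant genes of each library held 55.8% and 66.0% of untreated and treated mRNA reads, and 56.5% and 59.96% of untreated and treated footprints. Reads of the myosin heavy chain genes can be shared between near-identical copies. Myh13, a myosin of eye and larynx muscle, had 22.9% and 10.9% as many reads as Myh4 in untreated and treated mRNA and 24.8% and 20.5% in untreated and treated footprints, so values of single Myh genes are uncertain.

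The opening question was how dystrophin itself differed, since the vector acts on the dystrophin transcript. Dmd (NM_007868), which encodes dystrophin, the protein that links the actin cytoskeleton to the membrane complex of the fibre, was 3.63-fold higher (95% interval 2.45 to 5.63) in the treated mRNA library, from 25 reads untreated and 1959 treated. Its footprints were 4.74-fold higher (3.62 to 6.24), from 80 reads untreated and 183 treated. Dmd was among the 12 genes highest in treated footprints. Its translation efficiency ratio of 1.32 (0.827 to 2.12) had an interval that held 1 with TMM, but with the listed totals it was 2.03 (1.27 to 3.24), with the upper quartile 1.61 (1.01 to 2.58), without the 20 most abundant genes 1.72 (1.07 to 2.75) and with the authors' constants 2.02 (1.26 to 3.23). Utrn (NM_011682), which encodes the dystrophin relative utrophin, was 1.98-fold higher (1.25 to 3.36) in treated mRNA, while its footprint ratio was 1.02 (0.847 to 1.23). The mRNA interval of Utrn held 1 with the listed totals, at 1.26 (0.791 to 2.14), and also with the upper quartile and with the authors' constants. Its translation efficiency was 1.88-fold lower (1.15 to 3.09) with TMM, but its interval held 1 with the listed totals, at 1.23-fold lower (0.7496 to 2.02), and also with the upper quartile, without the 20 most abundant genes and with the authors' constants. Dmd, Utrn and Lama2, a laminin gene named below, are among 29 long-transcript genes, a list chosen after the data were seen, whose mRNA median lay 1.22 log2 units above the median gene. Gene counts cannot show which exons the reads covered, so exon 2 was not assessed. With the authors' library constants the Dmd log2 ratio was 0.98 in mRNA and 1.97 in footprints, against 1.86 and 2.24, and that of Utrn mRNA was 0.10 against 0.99.

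The mRNA comparison asked which transcripts differed between treated and untreated muscle. Pdk4, a kinase that holds back pyruvate entry into the citrate cycle, was highest in the treated library at 17.5-fold (10.4 to 32.0), from 14 untreated reads. The actin-binding repeat genes Xirp1 and Xirp2, expressed at sites of mechanical stress, were 11.1-fold (7.74 to 16.6) and 10.3-fold (8.73 to 12.3) higher. Tnnt1, the slow skeletal troponin T, was 42.0-fold lower (23.5 to 77.3), and Casq2, the cardiac and slow-fibre calsequestrin, was 22.0-fold lower (16.5 to 29.2). Col1a1, a chain of the main fibrillar collagen, was 18.5-fold lower (16.9 to 20.2). Of 996 genes compared, 317 were higher and 247 lower in the treated library.

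Several of the other highest mRNAs encode very large proteins. Wnk1, a kinase of ion transport, was 9.0-fold higher (5.82 to 14.7), Dst, a cytoskeletal linker, 6.61-fold (5.47 to 8.06) and Huwe1, a ubiquitin ligase, 7.93-fold (5.18 to 12.8). Neb, the thin-filament ruler nebulin, was 5.66-fold higher (5.41 to 5.94), Cmya5 5.37-fold (4.86 to 5.94) and Ttn 4.82-fold (4.73 to 4.91). Abra, an activator of actin and serum response factor signalling, was 8.42-fold higher (5.10 to 15.1) and Scn4a, the muscle sodium channel, 7.07-fold (4.82 to 10.8). Among the lowest, Fhl1, a LIM-domain protein of the sarcomere, was 9.65-fold lower (8.52 to 10.9), Myl4, an embryonic and atrial myosin light chain, 11.7-fold (7.36 to 18.3) and Lgals1, which encodes galectin-1, 7.60-fold (6.53 to 8.83). Hmgn2, a nucleosome-binding protein, was 11.3-fold lower (6.5 to 19.1), Hn1 10.4-fold (6.45 to 16.5) and Myom3, an M-band protein, 10.1-fold (5.97 to 16.8). Col3a1 was 6.70-fold lower (6.25 to 7.17), Atp5j, a subunit of the ATP synthase, 6.34-fold (5.61 to 7.14) and Actc1, cardiac alpha-actin, 6.23-fold (5.80 to 6.68). Actin and histone genes also have near-identical copies that could share reads.

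Scaling moved all mRNA ratios together. The median log2 ratio of the listed genes was 0.06 with TMM, −0.60 with the listed totals, −0.34 with the upper quartile, −0.25 without the 20 most abundant genes and −0.83 with the authors' constants. Genes higher in the treated library made up 56.2% of the called genes with TMM and 24.2%, 35.7%, 40.7% and 16.8% in those 4 settings. List medians are therefore given relative to the median listed gene, a difference that a change of scaling leaves as it is, and calls per list are those under TMM. With the listed totals the mRNA medians themselves lay below 0 for the fast contractile, sarcomere scaffold, glycolysis, translation factor, immediate early and ribosomal protein lists. With the authors' constants this held also for the dystrophin-associated complex and calcium handling.

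Markers of macrophages and innate immune cells were lower in treated mRNA. Of 11 listed members, 8 were lower and 0 higher, and their median lay 2.04 log2 units below the median listed gene, at percentile 0.01 of the matched random lists. The complement genes C1qa and C1qb were 6.16-fold (3.96 to 9.32) and 5.18-fold (3.21 to 8.08) lower, Ctss, a lysosomal protease of antigen-presenting cells, 4.96-fold (3.42 to 7.02) and Lyz2, the macrophage lysozyme, 4.14-fold (3.09 to 5.45). Each of the 3 listed members of interferon response and antigen presentation was lower. B2m, the shared subunit of class I molecules, was 2.53-fold lower (1.74 to 3.58), H2-K1 1.68-fold (1.08 to 2.5) and H2-D1 1.59-fold (1.04 to 2.34), and the list stood at percentile 6.12. Of 22 extracellular matrix members, 10 were lower and 4 higher, with the median 0.63 below the median gene at percentile 0.09. Col1a2 was 6.19-fold lower (5.59 to 6.84) and Col5a2 5.73-fold (4.70 to 6.93), both fibrillar collagen chains. Of 6 members of the immature and regenerating fibre list, 3 were lower and 1 higher, at percentile 11.8. The myosin heavy chain genes of that list, Myh3 and Myh8, were called neither way, with log2 ratios of 0.15 and −0.20. The myosin light chain gene Myl4 was among the 3 lower. Peg3, an imprinted zinc finger gene, was 1.74-fold lower (1.34 to 2.24), while Myf6, a myogenic transcription factor, was 1.92-fold higher (1.24 to 3.16).

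Muscle fibre lists lay mostly on the higher side in treated mRNA. Of 31 sarcomere scaffold genes, 16 were higher and 6 lower, with the median 0.56 above the median gene at percentile 90.4. Of 15 calcium handling genes, 8 were higher and 0 lower (median 0.66 above, percentile 78.6). Cacna1s, the voltage sensor of excitation-contraction coupling, was 5.21-fold higher (4.17 to 6.60), Jph1, which ties the calcium store to the membrane, 2.82-fold (1.89 to 4.42) and Ryr1, the calcium release channel, 2.04-fold (1.90 to 2.19). Of 18 fast contractile genes, 8 were higher and 0 lower (median 0.49 above, percentile 76.0). The myosin light chain kinases Mylk4 and Mylk2 were 4.22-fold (3.12 to 5.87) and 3.81-fold (2.84 to 5.23) higher, the calcium pump Atp2a1 2.11-fold (2.04 to 2.18) and Actn3, a fast-fibre Z-disc protein, 2.03-fold (1.89 to 2.18). Of 6 slow contractile genes over the read minimum, 3 were lower and 1 higher, at percentile 10.1. Their median was 0.97 below the median gene, and some of these genes had few reads. Its log2 ratio went from −0.92 to 0.49 at a minimum of 200 summed reads, which left out Tnnt1 and Tpm3. Most summed reads come from the deeper treated library, so this minimum tends to leave out genes that are low there. The turn therefore cannot tell whether few reads made the median low. Tpm3, a slow tropomyosin, was 4.76-fold lower (2.74 to 7.90), and Myh7, the slow myosin, was 4.07-fold higher (3.36 to 4.98).

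In the dystrophin-associated complex 7 of 10 listed members were higher and 0 lower, with a median 0.79 above the median gene at percentile 92.9, while the 29 long-transcript genes lay 1.22 above it. Lama2, a laminin chain of the fibre's basement membrane, was 3.91-fold higher (2.52 to 6.41) and Dag1, the dystroglycan gene, 3.90-fold (2.39 to 6.84). Of 7 atrophy and muscle mass genes, 5 were higher and 0 lower, with a median 1.00 above the median gene at percentile 99.4. Trim63, a muscle ubiquitin ligase, was 7.35-fold higher (4.58 to 12.6), Amd2, a copy of a polyamine synthesis gene, 2.89-fold (2.01 to 4.29), Sqstm1, an autophagy receptor, 2.17-fold (1.66 to 2.91) and Trim54 2.08-fold (1.23 to 3.82). Of 7 immediate early and heat shock genes, 2 were higher and 1 lower, at percentile 25.3. Nr4a1, an orphan nuclear receptor induced by activity, was 4.79-fold higher (3.06 to 7.97) and the endoplasmic reticulum chaperone Hspa5 2.23-fold (1.48 to 3.53). The chaperone Hsp90aa1 was 1.61-fold lower (1.11 to 2.26), and Hsp90ab1 had an mRNA value 1.35-fold lower (1.19 to 1.53), under the fold threshold.

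Energy metabolism was split. Of 60 nuclear oxidative phosphorylation genes, 24 were lower and 6 higher, with the median 0.42 below the median gene at percentile 0. Uqcrq, a subunit of complex III, was 5.54-fold lower (3.90 to 7.73), Cox5a, of cytochrome oxidase, 4.84-fold (4.14 to 5.62) and Cycs, cytochrome c, 4.01-fold (3.48 to 4.62). Of 35 citrate cycle and fatty acid oxidation genes, 7 were higher and 9 lower (percentile 3.29). Sucla2 was 2.76-fold higher (1.99 to 3.95), whereas Dlst, another citrate cycle enzyme, was 3.23-fold lower (2.64 to 3.92) and Mdh2, malate dehydrogenase, 2.12-fold (1.85 to 2.42). Of 19 glycolysis and glycogen genes, 8 were higher and 0 lower, with the median 0.15 above the median gene at percentile 25.1. Over all 996 genes compared, 317 were higher. Ppp1r3a, a glycogen-targeting phosphatase subunit, was 5.24-fold higher (4.02 to 6.96) and the phosphorylase kinase subunits Phkg1 and Phkb 3.53-fold (2.35 to 5.59) and 3.49-fold (2.55 to 4.92).

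Genes of the translation machinery were more often higher than lower in treated mRNA. Of 67 cytosolic ribosomal protein genes, 27 were higher and 7 lower, with the median 0.35 above the median gene at percentile 74.8. Rplp0 was 4.04-fold higher (2.86 to 5.92), Rpl4 3.36-fold (2.5 to 4.63) and the muscle paralog Rpl3l 3.83-fold (2.44 to 6.37). Of 23 translation factors, 10 were higher and 1 lower (median 0.50 above, percentile 90.2). The initiation scaffolds Eif4g2, Eif4g3 and Eif4g1 were 5.71-fold (4.24 to 7.86), 4.66-fold (2.86 to 8.17) and 3.99-fold (2.99 to 5.43) higher, and the elongation factor Eef1a1 was 2.08-fold lower (1.87 to 2.31). Ribosomal protein genes have many processed pseudogenes, and how reads were divided between copies is not given in the sources used here. Genes chosen with the fewest untreated mRNA reads, 14 to 19, had a median mRNA log2 ratio of 0.31, against −0.13 for those with 60 to 199. Random lists matched on the untreated mRNA count instead of mean expression, chosen after the data were seen, put 7 of 16 lists outside their central 95% in mRNA, against 4. The percentile became 99.8 for sarcomere scaffold, 99.2 for ribosomal proteins, 97.97 for calcium handling and 97.9 for fast contractile genes, 42.0 for the citrate cycle list and 95.5 for atrophy genes.

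The footprint comparison asked which genes held more or fewer ribosomes in treated muscle. Pdk4 footprints were 35.2-fold higher (31.2 to 39.7). Abra, Trim63 and Nr4a1 were 10.3-fold (9.32 to 11.4), 10.3-fold (9.26 to 11.4) and 10.1-fold (8.97 to 11.3) higher. Fibrillar collagens were among the lowest. Col1a1 was 19.7-fold lower (18.2 to 21.3), Col3a1 17.9-fold (16.6 to 19.3), Col1a2 10.02-fold (9.35 to 10.8) and Col5a2 8.42-fold (7.24 to 9.84). Tnnt1 was 14.3-fold lower (9.25 to 23.2). Of 999 genes compared, 199 were higher and 262 lower in the treated library.

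**Figure D1:**
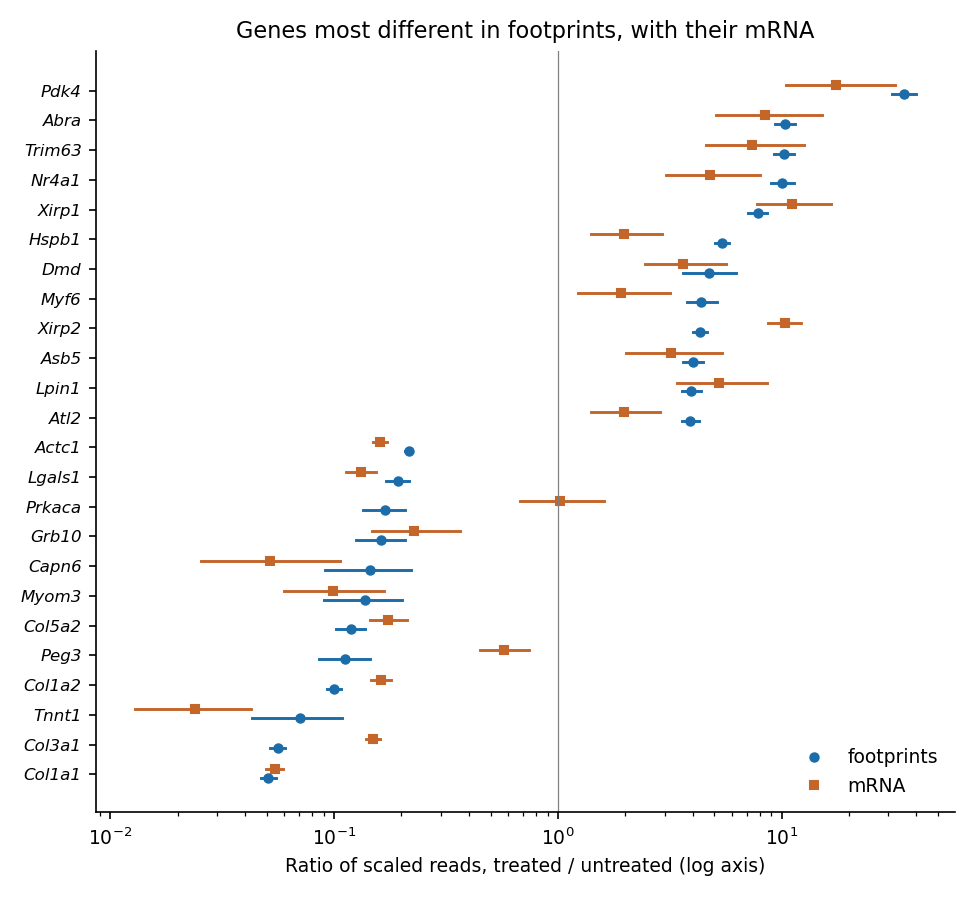
Ratios of scaled reads, treated over untreated, on a log axis for the 12 highest and 12 lowest genes in footprints, with circles for footprints, squares for mRNA and bars for 95% counting intervals from 1 library per group. Pdk4 stands at 35.2-fold higher and Col1a1 at 19.7-fold lower in footprints, and Prkaca differs in footprints with an mRNA ratio of 1.02.

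Other genes with higher footprints were Xirp1 at 7.80-fold (7.11 to 8.58), the small heat shock protein gene Hspb1 at 5.41-fold (5.03 to 5.82), Myf6 at 4.38-fold (3.76 to 5.12) and Xirp2 at 4.31-fold (4.01 to 4.65). Asb5, a ubiquitin ligase adaptor, was 4.02-fold higher (3.62 to 4.47), Lpin1, a phosphatidate phosphatase of lipid synthesis, 3.95-fold (3.57 to 4.37) and Atl2, which shapes the endoplasmic reticulum, 3.91-fold (3.57 to 4.28). Among the lowest, Peg3 was 8.91-fold lower (6.93 to 11.7), Myom3 7.28-fold (4.96 to 11.1), Capn6 6.89-fold (4.51 to 11.0) and Grb10, an imprinted growth factor receptor adaptor, 6.17-fold (4.82 to 8.02). Prkaca, the catalytic subunit of protein kinase A, was 5.94-fold lower (4.80 to 7.42), Lgals1 5.19-fold (4.62 to 5.85) and Actc1 4.64-fold (4.49 to 4.80).

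Extracellular matrix footprints were lower in treated muscle for 20 of 22 listed members and higher for 0, with the median 1.62 log2 units below the median gene, at percentile 0. Markers of macrophages were lower for 10 of 11 members and higher for 0 (median 1.00 below, percentile 0.08). Ctss was 3.90-fold lower (3.25 to 4.71), C1qa 2.59-fold (2.03 to 3.33), Lcp1, a leukocyte actin bundler, 2.37-fold (1.97 to 2.88) and the lysosomal protease Ctsb 2.12-fold (1.98 to 2.27). All 3 antigen presentation genes were lower, H2-D1 by 2.43-fold (2.22 to 2.68), H2-K1 by 2.34-fold (2.14 to 2.56) and B2m by 2.12-fold (1.96 to 2.29), at percentile 2.35. Of 6 immature fibre genes, 3 were lower and 1 higher (percentile 6.53), with Myl4 2.17-fold lower (2.0 to 2.36). Myh3 and Myh8 were again called neither way, with log2 ratios of 0.08 and −0.06.

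Sarcomere scaffold footprints were higher for 16 of 31 genes and lower for 4, with the median 0.62 above the median gene at percentile 99.99. Des, the muscle intermediate filament desmin, went the other way at 4.39-fold lower (4.18 to 4.61). Of 15 calcium handling genes, 8 were higher and 2 lower (median 0.73 above, percentile 99.9). Jph2 was 2.86-fold higher (2.31 to 3.54), Scn4a 2.5-fold (2.30 to 2.72) and Stac3, a coupling adaptor, 2.24-fold (1.98 to 2.53), while Srl, which encodes sarcalumenin, was 2.91-fold lower (2.73 to 3.11). Of 19 glycolysis and glycogen genes, 8 were higher and 1 lower (median 0.47 above, percentile 97.3). Phkg1 was 3.59-fold higher (3.30 to 3.91), Ppp1r3a 3.40-fold (3.16 to 3.65) and Pfkm, the muscle phosphofructokinase, 2.40-fold (2.36 to 2.44). Gapdh, which has many pseudogenes, was 3.09-fold lower (3.02 to 3.17). Of 18 fast contractile genes, 4 were higher and 4 lower (percentile 13.4), with Mylk2 3.79-fold (3.55 to 4.06), Mylk4 3.16-fold (2.98 to 3.35) and the calcium buffer Pvalb 2.75-fold (2.69 to 2.80) higher and skeletal alpha-actin Acta1 2.34-fold lower (2.31 to 2.38). Of 7 slow contractile genes, 1 was higher and 2 lower (percentile 28.3). Myoglobin, Mb, was 2.23-fold higher (2.13 to 2.34), Casq2 was 2.13-fold lower (1.97 to 2.32), and Myh7 had a value 1.10-fold lower (1.07 to 1.12).

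Ribosomal protein footprints were lower for 48 of 67 genes and higher for 2, with the median 0.92 below the median gene at percentile 0. Rplp1 was 5.56-fold lower (3.91 to 8.14), Rps3a 4.36-fold (3.48 to 5.54), Rpl10a 4.00-fold (3.17 to 5.10) and Rplp0 3.65-fold (2.81 to 4.80). Of 23 translation factors, 4 were higher and 7 lower (percentile 22.9). Tpt1 was 4.17-fold lower (3.59 to 4.87), Eef1b2 3.36-fold (2.55 to 4.49), Gnb2l1, the ribosome scaffold RACK1, 3.20-fold (2.67 to 3.86) and Eef2, an elongation factor, 2.55-fold (2.35 to 2.76). Of 60 oxidative phosphorylation genes, 7 were higher and 11 lower (percentile 8.70). Ndufa4 was 2.93-fold higher (2.74 to 3.13), and the complex I subunits Ndufa6, Ndufb9 and Ndufv2 were 2.59-fold (1.96 to 3.47), 2.48-fold (2.22 to 2.77) and 2.11-fold (1.92 to 2.33) lower. Of 35 citrate cycle and fatty acid genes, 7 were higher and 2 lower (percentile 86.5). Hadhb, a fatty acid oxidation enzyme, was 1.82-fold higher (1.69 to 1.96), Fabp3, a fatty acid carrier, 1.77-fold (1.61 to 1.94) and Dlat, of pyruvate dehydrogenase, 1.76-fold lower (1.57 to 1.97).

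Of 7 atrophy genes 3 were higher and 1 lower in footprints (percentile 90.6), with Trim54 2.44-fold (2.16 to 2.76) and Sqstm1 2.30-fold (2.13 to 2.48) higher and the autophagosome gene Map1lc3a 2.32-fold lower (1.96 to 2.75). Of 7 immediate early and heat shock genes, 1 was higher and 1 lower (percentile 18.98), the latter Hsp90ab1 at 1.5-fold (1.42 to 1.59). In the dystrophin-associated complex 2 of 10 genes were higher and 0 lower (percentile 62.6). Besides Dmd this was Capn3, a muscle protease, at 1.64-fold (1.42 to 1.88). Lama2 had a value 1.46-fold lower (1.34 to 1.59), under the fold threshold. With the authors' constants, genes higher in treated footprints made up 23.8% of calls against 43.2% with TMM, and the median log2 ratio of the listed genes was −0.29 against −0.02. With random lists matched on the untreated mRNA count, glycolysis stood at percentile 99.03 in footprints and antigen presentation at 3.57.

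Across 995 genes over the minimum in both assays, mRNA and footprint log2 ratios correlated with a Pearson r of 0.40 and a Spearman rho of 0.32. Genes are not independent replicates, and no p-value is given. Called higher in both were 111 genes, against 63.1 if the calls were independent, and lower in both were 101, against 64.3. Opposite calls were fewer than that number, with 58 genes higher in mRNA and lower in footprints against 82.8, and 14 genes lower in mRNA and higher in footprints against 49.0. Among the 115 genes with at least 100 untreated mRNA reads, a choice added after the data were seen, r was 0.68.

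**Figure D2:**
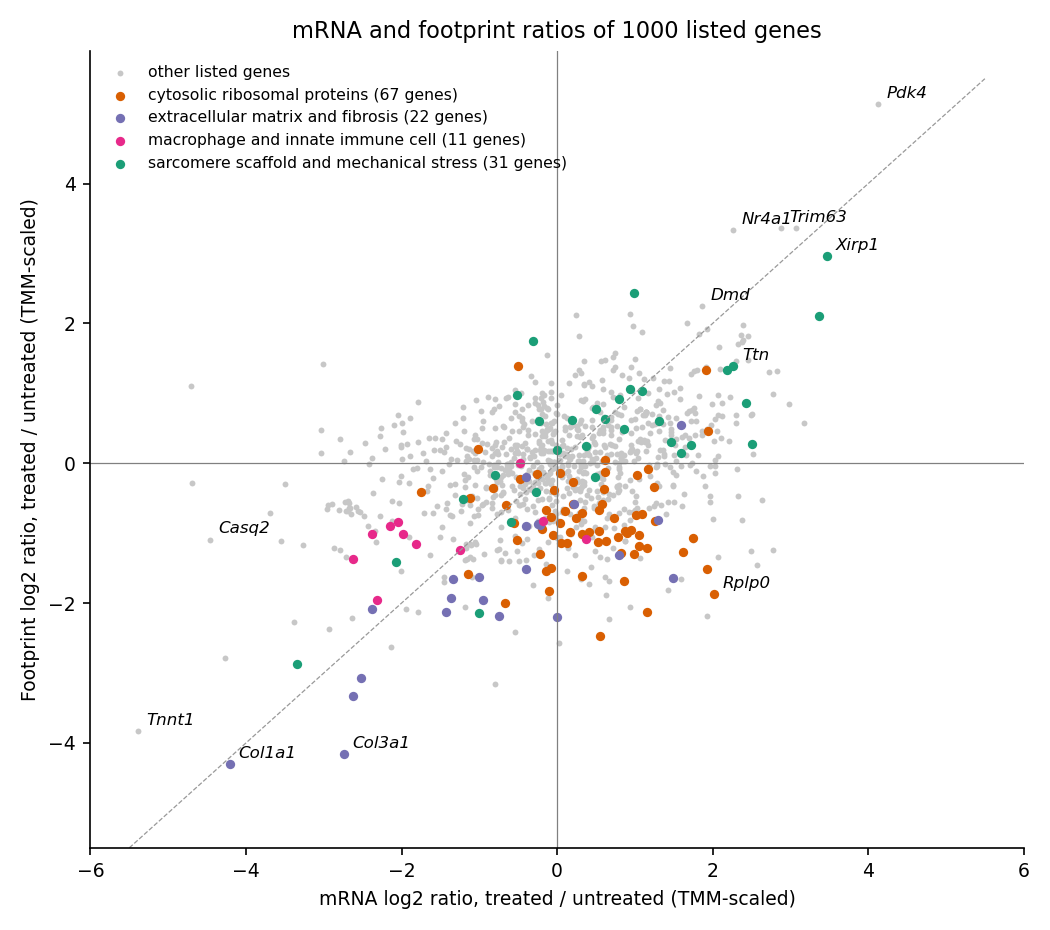
Each point is 1 of 1000 listed genes, with the treated over untreated log2 ratio of mRNA on the horizontal axis and of footprints on the vertical axis, both TMM-scaled, 4 gene lists in colour and a dashed line of equal ratios. Ribosomal protein genes lie mostly below the horizontal zero line (48 of 67 lower in footprints), and collagens lie at the lower left.

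Translation efficiency asked where footprints and mRNA differed by unlike amounts. Sh3glb1, a membrane-curvature protein of autophagy, was 16.8-fold lower (10.3 to 27.2), and Ybx1, an mRNA-binding protein, 15.8-fold lower (9.85 to 25.5). Rplp0 was 14.4-fold lower (9.38 to 22.2), Zfp106 13.2-fold (9.26 to 18.9), Ccng1 15.6-fold (9.10 to 26.8) and Gnas, the stimulatory G protein, 9.32-fold (7.41 to 11.7). At the other end Selk, a selenoprotein of the endoplasmic reticulum, was 21.7-fold higher (13.4 to 35.0), Casq2 10.3-fold (7.75 to 13.7), Crip1 11.5-fold (6.65 to 19.9), Tagln2 8.96-fold (5.59 to 14.4), 9130011J15Rik 9.27-fold (5.17 to 16.6) and Atp5j 7.08-fold (6.12 to 8.19). Of 995 genes, 259 were higher and 317 lower.

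Ribosomal protein genes had lower translation efficiency in the treated libraries for 48 of 67 members and higher for 4, with the median 1.10 below the median gene at percentile 0. Rps3a was 9.52-fold lower (6.40 to 14.2) and Rpl4 6.99-fold (5.05 to 9.68). Within each condition, the ribosomal protein median of footprints per mRNA lay 0.52 log2 units under the median gene in untreated muscle and 1.68 under it in treated muscle. Translation factors were lower for 12 of 23 and higher for 0 (median 0.63 below, percentile 1.19). Tpt1 was 7.91-fold lower (6.12 to 10.2), Eef2 5.31-fold (4.43 to 6.36), Gnb2l1 4.98-fold (3.41 to 7.28) and Eif4g2 3.45-fold (2.49 to 4.78). Extracellular matrix genes were lower for 15 of 22 and higher for 0 (percentile 3.26), with the microfibril gene Fbn1 8.50-fold (5.33 to 13.6), fibronectin Fn1 4.53-fold (3.43 to 5.97), the basement membrane gene Nid1 4.23-fold (2.84 to 6.28) and Mmp2, a matrix protease, 4.18-fold (2.51 to 6.96) lower.

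Oxidative phosphorylation genes were higher in translation efficiency for 24 of 60 and lower for 10. Their median lay 0.51 above the median gene, at percentile 99.99. In footprints their median lay 0.06 below the median gene and in mRNA 0.42 below it. The ratio thus reflects mainly their lower mRNA values. Uqcrq was 6.84-fold higher (4.83 to 9.68), Ndufc1 6.04-fold (3.79 to 9.62) and Cycs 4.71-fold (3.98 to 5.57). Of 35 citrate cycle and fatty acid genes, 16 were higher and 4 lower (percentile 97.9), with Dlst 3.31-fold (2.66 to 4.12), Fabp3 2.98-fold (2.30 to 3.85), Mdh2 2.39-fold (2.07 to 2.75) and Mdh1 2.26-fold (1.93 to 2.65) higher. Of 6 slow contractile genes 4 were higher and 2 lower (percentile 99.7). Tpm3 was 4.17-fold (2.51 to 6.93) and Tnnt1 2.97-fold (1.48 to 5.96) higher, and Myh7 was 4.45-fold lower (3.67 to 5.40). This percentile rests partly on few reads. Tpm3 had 19 untreated and 86 treated mRNA reads, and Tnnt1 had 37 and 19. Both fall under the alternative minimum of 200 summed reads, at which the mRNA median of this list changed sign. That minimum tends to leave out genes that are low in the deeper treated mRNA library, so the change of sign cannot tell whether few reads are the cause. Of 11 macrophage genes 6 were higher and 1 lower (percentile 98.6). Their median lay 2.04 below the median gene in mRNA and 1.00 below it in footprints. The ratio was thus higher because mRNA was lower by more, not because footprints were higher. C1qb was 2.61-fold (1.62 to 4.20), H2-Eb1 2.41-fold (1.62 to 3.59) and Lyz2 2.34-fold (1.75 to 3.11) higher, and Ctsb was 2.70-fold lower (1.95 to 3.74).

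Of 18 fast contractile genes 2 were higher and 7 lower in translation efficiency (percentile 15.8), with Mybpc2 3.35-fold (3.07 to 3.65), Actn3 3.16-fold (2.93 to 3.42), creatine kinase Ckm 2.25-fold (2.14 to 2.36) and Tpm1 2.16-fold (2.07 to 2.25) lower. Of 31 scaffold genes 7 were higher and 9 lower (percentile 71.0). Neb was 4.70-fold (4.47 to 4.93), Cmya5 2.95-fold (2.65 to 3.28) and Ahnak 2.74-fold (2.38 to 3.14) lower, and Tcap, a titin-binding Z-disc protein, 4.17-fold higher (3.59 to 4.85). Of 15 calcium handling genes 4 were higher and 5 lower (percentile 58.8), with Cacna1s 9.06-fold (7.13 to 11.5), Srl 3.17-fold (2.71 to 3.70), Jph1 3.01-fold (1.94 to 4.68) and Scn4a 2.78-fold (1.88 to 4.11) lower. In the dystrophin-associated complex 1 of 10 was higher and 5 lower (percentile 31.1). Lama2 was 5.57-fold (3.57 to 8.68), Dag1 3.87-fold (2.35 to 6.36) and the integrin Itgb1 2.21-fold (1.56 to 3.14) lower, and Capn3 was 1.68-fold higher (1.16 to 2.44). Of 6 immature fibre genes 2 were higher and 1 lower (percentile 90.6), with Myl4 5.43-fold (3.51 to 8.38) and Myf6 2.34-fold (1.47 to 3.71) higher and Peg3 5.04-fold lower (3.54 to 7.17).

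Of 19 glycolysis genes 1 was higher and 2 lower in translation efficiency (percentile 91.5), with Hk2, a hexokinase, 3.01-fold higher (2.32 to 3.91) and Gapdh 4.74-fold lower (4.48 to 5.01). Of 7 atrophy genes 3 were lower and 0 higher (percentile 60.2), namely Map1lc3a by 2.48-fold (1.49 to 4.11), Amd2 by 2.22-fold (1.48 to 3.33) and Ddit4l by 2.11-fold (1.31 to 3.38). Of 7 immediate early and heat shock genes 2 were higher and 2 lower (percentile 56.2), with Nr4a1 2.15-fold (1.36 to 3.41) and Hsp90aa1 2.02-fold (1.41 to 2.90) higher and Hspa5 1.75-fold lower (1.16 to 2.66). Of the 3 antigen presentation genes 1 was lower (percentile 45.8), H2-D1 at 1.5-fold (1.02 to 2.22), and this direction turned with the listed totals and with the authors' constants. Genes higher in translation efficiency made up 45.0% of calls with TMM, 73.9% with the listed totals, 59.97% with the upper quartile, 63.8% without the 20 most abundant genes and 73.8% with the authors' constants. The median log2 ratio moved from −0.10 to 0.51, 0.18, 0.27 and 0.51 in the same order. With random lists matched on the untreated mRNA count, the percentile in translation efficiency was 93.1 for the citrate cycle list, 97.1 for macrophage and 0.83 for extracellular matrix genes.

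**Figure D3:**
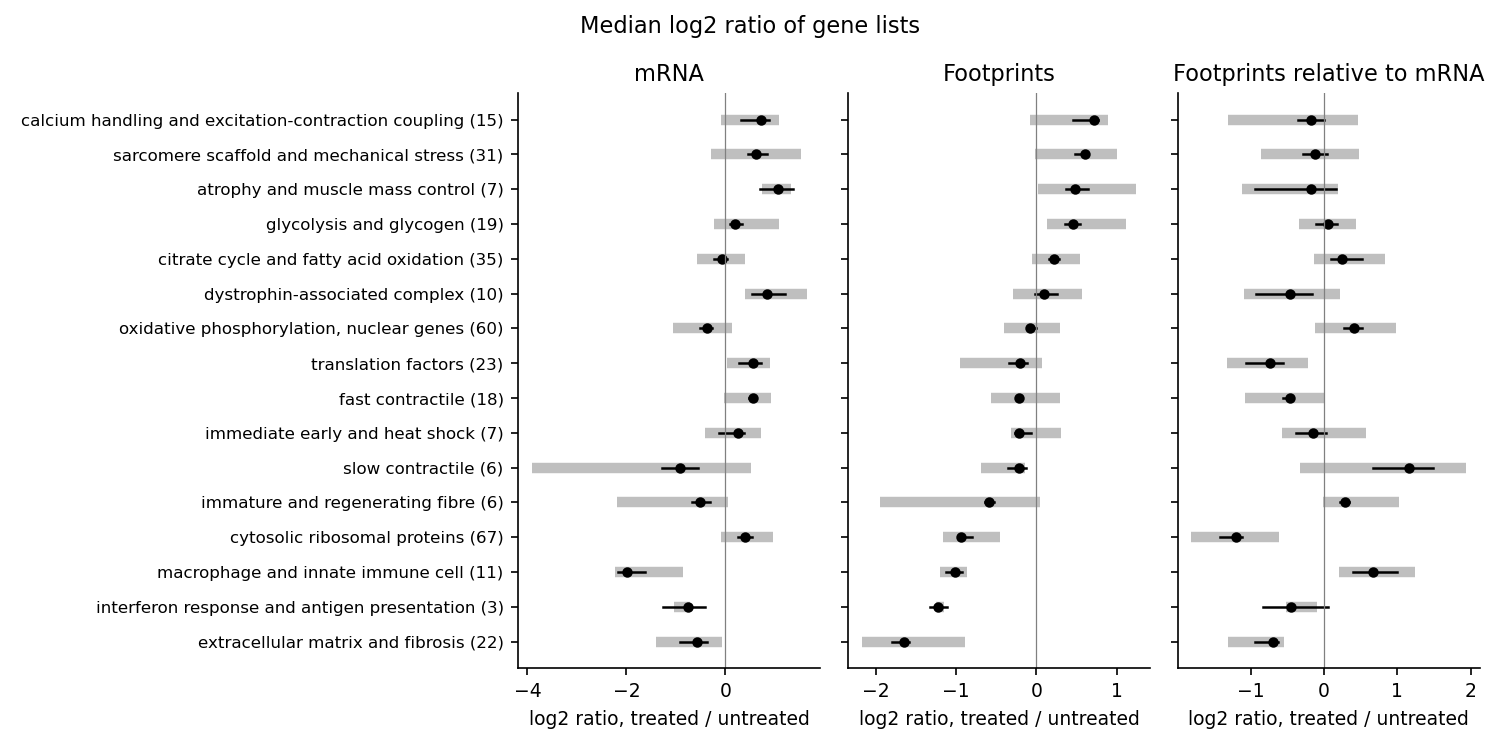
Median log2 ratio, treated over untreated and TMM-scaled, of the 16 gene lists with at least 3 listed members (number of listed genes in brackets) in mRNA, footprints and footprints relative to mRNA, with black bars for 95% counting intervals and grey bars from the 25th to the 75th percentile of the genes. Extracellular matrix genes are lowest in footprints, at 1.62 below the median gene. Ribosomal protein genes are low in footprints and not in mRNA. With the listed totals and the authors' constants their mRNA median itself lies below 0. Relative to the median gene it stays 0.35 above in mRNA and 0.92 below in footprints under each scaling.

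Lists of other cell types had few listed members. Of the adipocyte list, Plin4, a lipid droplet coat protein, was 5.02-fold higher (3.21 to 8.36) in mRNA and 3.25-fold higher (2.77 to 3.83) in footprints, and Fabp4, a fatty acid carrier of fat cells, was 4.34-fold higher (3.55 to 5.34) in footprints and 3.79-fold higher (2.20 to 6.54) in translation efficiency. Acta2, smooth muscle actin, was 1.62-fold lower (1.25 to 2.08) in mRNA and had a footprint value 1.33-fold lower (1.28 to 1.37). Thbs4, of the tendon list, had a footprint value 1.47-fold lower (1.37 to 1.58) and a translation efficiency 1.85-fold lower (1.25 to 2.74). The Y-linked genes Ddx3y and Eif2s3y were 2.52-fold (2.19 to 2.89) and 1.72-fold (1.39 to 2.14) higher in treated footprints. In mRNA Ddx3y was 1.65-fold higher (1.07 to 2.68), a direction that turned with the authors' constants. Eif2s3y translation efficiency was 1.96-fold higher (1.11 to 3.45). No member of the T and B lymphocyte, mitochondrially encoded, red blood cell, Schwann cell and nerve, or noncoding RNA lists was among the listed genes.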

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

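The tests against transcript length and against matched low-read lists were chosen after the result was seen, and the test among well-read genes was planned before it.

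Of the lists whose translation efficiency median lay outside the central 95% of the random lists, 3 were flagged. Relative to the median gene, their medians had opposite signs in mRNA and in footprints, which a change of scaling leaves as it is. Not taken relative to it, the mRNA medians of 2 of them, translation factors and ribosomal proteins, depended on scaling. With the listed totals these lay below 0 like their footprints, at −0.10 and −0.25, and with the authors' constants at −0.32 and −0.48. With those constants the footprint median of the citrate cycle list was −0.06. The difference between the assays was not tested, since each rests on 1 library per group. Citrate cycle and fatty acid oxidation genes had a median translation efficiency log2 ratio of 0.25. Their mRNA median of −0.07 had an interval that held 0 (−0.22 to 0.03), and with random lists matched on the untreated mRNA count, chosen after the data were seen, they stood at percentile 93.1, inside the central 95%. Translation factors, which include the elongation factors and initiation scaffolds, had a median of −0.74. Cytosolic ribosomal protein genes had a median of −1.20, with 48 of 67 members lower and 4 higher. These 3 medians are under TMM, where the median gene lay at −0.10, and are not relative to it. They were 0.86, −0.12 and −0.59 with the listed totals and 0.86, −0.13 and −0.59 with the authors' constants, while relative to the median gene they lay at 0.35, −0.63 and −1.10.

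The ribosomal protein pattern is the widest of these: of 67 genes, footprints of 48 were lower and mRNA reads of 27 were higher under TMM. Over all genes, 262 of 999 were lower in footprints and 317 of 996 were higher in mRNA. The list stood at percentile 0 in footprints but at 74.8 in mRNA, or 99.2 with lists matched on the untreated mRNA count. A shift shared by genes with as few untreated mRNA reads is argued against, because the lowest median of 10000 random lists matched on that count was −0.70. A bias against short transcripts in the untreated mRNA library, which would lower the translation efficiency ratio of short genes, is argued against too, because the oxidative phosphorylation genes, also short, had a translation efficiency median 0.51 above the median gene; a bias of the opposite direction is weighed under the long transcripts. Among genes with at least 50 untreated mRNA reads the 11 remaining ribosomal protein genes lay −0.46 from the median gene, between the bounds set beforehand, so few reads as part of the cause cannot be told apart from a difference in ribosome loading. Reads shared with pseudogenes, a difference between the single libraries and an effect of the vector treatment stay open as untested explanations.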

How the results depend on the processing

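The authors' constants, the genes with at least 100 untreated mRNA reads and the thinned libraries were chosen after the data were seen; the other settings were planned. With the listed totals, mRNA calls went from 317 higher and 247 lower to 148 and 464, and translation efficiency calls from 259 and 317 to 444 and 157. With the upper quartile 205 mRNA genes were higher. With the authors' constants mRNA calls were 110 and 543, translation efficiency calls 444 and 158, and 114 genes were higher in footprints, against 199. A minimum of 200 summed reads left 317 genes higher and 160 lower in mRNA, against 317 and 247. It removed lower calls alone, because most summed reads come from the deeper treated library and a gene low there has a low sum. The loss therefore does not show that the lower calls were the less reliable ones. A 2-fold threshold left 81 higher and 143 lower in footprints, against 199 and 262. Among 115 genes with at least 100 untreated mRNA reads, calls were 34 and 31 in mRNA, 25 and 33 in footprints and 23 and 30 in translation efficiency, fewer because fewer genes were compared, and r between assays was 0.68 against 0.40. With all libraries thinned to equal reads, 496, 484 and 376 genes passed the read minimum in mRNA, footprints and translation efficiency. Of these 213 genes were higher and 71 lower in mRNA, 124 and 94 higher and lower in footprints and 59 and 113 in translation efficiency, and r was 0.56. The mRNA split depends on the read minimum, since the median listed gene had only 25 untreated mRNA reads. At equal depth a gene with few untreated reads passes a summed minimum only with more treated reads. The split therefore does not show that most mRNA differences are increases. Translation efficiency calls need the same mRNA minimum and share this limit. For the scalings, the shift of the median gene shows the cause; for the correlations the cause was not tested.

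Signs turned for 3 named gene values whose interval excluded 1, of which Hspa8, 1.39-fold lower, was under the fold threshold. H2-D1 translation efficiency was 0.026 with the listed totals and 0.023 with the authors' constants, Hspa8 translation efficiency 0.14 and 0.13, and Ddx3y mRNA −0.16 with the authors' constants. Median-of-ratios scaling left all 230 named values and all 48 list medians within their main intervals. Without a minimum 46 of 48 list medians stayed within theirs, and with a minimum of 200 reads 44 did. The other scalings moved more: of the list medians 35 with the listed totals, 35 with the upper quartile, 30 without the 20 most abundant genes and all 48 with the authors' constants, and of the named values 115, 75, 60 and 179 in the same order, besides the turned ones. Depth in the untreated mRNA library limits most mRNA and translation efficiency ratios. A replicate test with DESeq2, leaving out replicates and a replicate block were not run, as each group had 1 library. No paired analysis was possible because the groups share no replicate numbers with 2 or more libraries each.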

Other observations

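The tests on long and short transcripts, and the bound on the footprint spread of the long ones, were chosen after the results were seen, while the test of collagens against other fibroblast genes was written before its result. The histone genes were also singled out after their values were seen.

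Histone genes, whose mRNAs mostly lack a poly(A) tail, were lower in treated mRNA for 13 of 16 listed members and higher for 0, with a median log2 ratio of −2.67. In footprints 11 were lower and 3 higher, with a median of −0.63. All 16 were higher in translation efficiency, with a median of 2.05. Many histone genes are near-identical in sequence, so the 16 values are not independent of each other.

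Of 22 extracellular matrix genes, 20 were lower and 0 higher in footprints, while in mRNA 10 were lower, 4 higher and 8 neither, with Dcn at 1.60 and Mmp2 at 1.30. A lower share of all fibroblasts alike, as the only cause, is argued against by the fibroblast genes themselves. Col1a1, Col1a2 and Col3a1 had a median footprint log2 ratio of −4.16, against −0.59 for Dcn, Lum and Mmp2, a difference of −3.57, and Dcn, which encodes the collagen-binding decorin, was at 0.54. These collagens also ranked lowest of all genes in footprints by interval bound, so the size of the gap partly follows from the genes compared. The comparison does not address a lower share of only some fibroblasts. An effect of the vector treatment on collagen synthesis in the cells present, and a difference in age or state between the animals, stay open and were not tested, as the labels give no age, sex or number of animals.

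Very long transcripts such as those of Ttn, Neb, Dst, Huwe1 and Wnk1 were among the highest in treated mRNA, and a candidate explanation is a bias that favours long transcripts in that library. It was tested on 29 other long-transcript genes, Dmd, Utrn and Lama2 among them, listed from general knowledge without length data and chosen outside the 12 highest. Their mRNA median lay 1.22 above the median gene, with 23 higher and 0 lower. Their footprint median lay 0.13 above it, with 10 higher and 3 lower and log2 ratios from −2.20 for Fn1 to 2.24 for Dmd. The quartiles of these footprint ratios lay −0.32 and 0.74 from the median gene, against −0.58 and 0.49 for all genes. Their spread was thus ordinary, and the bound set on it cannot tell a bias from a real difference in mRNA. A high mRNA median with footprints near the median gene is what such a bias would give, but a real difference in mRNA is not excluded. Short transcripts went both ways: oxidative phosphorylation genes lay −0.42 from the median gene in mRNA, as such a bias would give, and the short histone genes were low as well, while ribosomal protein genes lay 0.35 above it, which length alone would not give. A treatment effect on long transcripts stays open. The mRNA and translation efficiency ratios of long genes, Dmd included, and of oxidative phosphorylation genes may carry such a bias.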
